A study of Mus musculus with 6 samples.

How the data were processed

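The data are counts of reads per gene in 6 bulk RNA libraries of the ischemic liver lobe, 3 from IRF8-cKO and 3 from WT mice. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with an NEBNext Ultra RNA kit for Illumina sequencing. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build mm10. The deposited table holds raw counts, whole numbers that the authors did not normalise, for 54532 genes with Ensembl identifiers, coordinates and lengths. The strand setting, the handling of multiply mapped reads and the annotation release are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies, such as the globin, H2, Mup, Cyp4a and ribosomal protein families, may therefore be split or shared. Of the identifiers, 54409 are in GENCODE M21 and 53499 of these have the same start and end there. Each gene count column was tied to its sample by the title, and each row names a gene.

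Groups were taken from the titles, and the numbers in the titles name the libraries. No number occurs in both groups, so no pairing was modelled. Counts of libraries of 1 group differed far beyond sampling noise (chi-square per degree of freedom 44.2 or more), so no library was taken as a second copy of another. This does not show that they are separate animals. Library totals of 14758237 to 16805830 counts were scaled by edgeR's TMM factors (WT 1.07, 0.786 and 0.942; IRF8-cKO 0.966, 0.990 and 1.32). Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13134 of 24095 genes with a read. CPM values are counts scaled to the TMM-adjusted library total in the usual way.

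Groups were compared with edgeR 4.0.16 in R 4.3.3, by a robust quasi-likelihood fit with group as the only term and a two-sided test, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Positive log2 fold changes mean higher in IRF8-cKO, and the standard error is the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 37.1%. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 39 lists with at least 5 tested members. Beside the count over all genes, members were counted at 0.05 after adjustment over the list alone. These counts were not corrected for the number of lists, and members that move together are not separate support. Of all 13134 genes tested, 3169 had an unadjusted p under 0.05 in the edgeR test. The lists come from general knowledge of liver, injury and interferon biology and were not chosen on these samples. Some genes are in several lists, such as Irf7 in the interferon and IRF lists. Principal components and correlations used log2 CPM. The first component took 52.0% and the second 18.7% of the variance.

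The groups, the test, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule takes Irf8 first. It then takes, in each direction, the 12 protein-coding genes with the largest log2 fold change among those with adjusted p under 0.05, mean log2 CPM of at least 1 and CPM that do not overlap between groups. Each called list adds up to 4 members with the lowest p. Every other list described adds up to 2 members with adjusted p under 0.05, or else the member with the lowest p. Tnf, Il1b, Il6, Cxcl1, Cxcl10, Ccl2, Saa1, Becn1, Map1lc3b, Sqstm1, Alb, Cyp7a1, Xist and Ddx3y were always included. A few genes that the rule takes are not reported here.

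Alternatives were median-of-ratios, upper-quartile and total-count scaling, no low-count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without library weights, a fit without robust shrinkage, removal of the 10 genes with most reads, and each library left out in turn. For lists they were camera with an estimated correlation, fry and a prior count of 0.5. Corrections for gene length, for gene length with GC content (a lowess curve per library with span 0.5), and removal of mitochondrial genes were chosen after the data were seen. GC content was that of the longest GENCODE M21 transcript and was known for 99.9% of tested genes.

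The procedure was tested on simulated data: counts of the 13134 genes were drawn from the means, dispersions and library sizes of this comparison, with 200 genes changed. edgeR recovered 76% of the genes changed 4-fold and 3% of those changed 2-fold, and 6 of its 85 calls were false. DESeq2 recovered 83% and 14%, with 24 of 121 calls false. With a gene length trend added to the simulated data, stronger than that of the real data (Spearman 0.361 against 0.196), edgeR recovered 62% of the genes changed 4-fold and 14 of its 81 calls were false, and with the length correction 56% and 8 of 65. At this depth, spread between libraries and number of libraries, most 2-fold differences therefore go undetected. Which of these sets the limit was not tested. In data with independent genes, camera with the preset correlation called both seeded lists and 0 of the others, camera with an estimated correlation called 1 of the 2 seeded lists and 0 others, and fry called both and 1 list that was not seeded. The estimated correlation can therefore miss a true list change. Independent genes do not show how often the preset correlation gives false calls where genes of a list move together. In the real data estimated correlations ran from -0.07 for dendritic cell markers to 0.81 for mitochondrial mRNAs. They were 0.56, 0.16 and 0.58 for the immediate-early, inflammatory and neutrophil lists, against the preset 0.01. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.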

Results

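Gene expression was measured by bulk RNA sequencing in the ischemic lobe of mouse liver after 1 h of warm ischemia and 12 h of reperfusion, an injury model in which blood flow to part of the liver is clamped and then restored. The libraries came from C57BL/6 mice lacking interferon regulatory factor 8 (IRF8) in hepatocytes (libraries IRF8-cKO-71, IRF8-cKO-88 and IRF8-cKO-106) and from wild-type mice (libraries WT-14, WT-44 and WT-77), 3 libraries per group. The gene counts summed to 15235364, 14758237 and 16010064 reads in WT-14, WT-44 and WT-77 and to 16805830, 16385964 and 16415402 reads in IRF8-cKO-71, IRF8-cKO-88 and IRF8-cKO-106. The single comparison of the design asks how the injured liver transcriptome differs when hepatocytes lack IRF8. No uninjured liver was measured, so every value below is a level in injured tissue. The labels do not state that the numbered libraries are separate animals, and the p-values measure the spread between these samples.

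Irf8 (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694, plus strand, mm10), the targeted gene and a transcription factor best known from myeloid cells, was lower in each IRF8-cKO library than in each WT library. It was covered by 152, 110 and 155 reads in WT-14, WT-44 and WT-77 and by 92, 109 and 90 reads in IRF8-cKO-71, IRF8-cKO-88 and IRF8-cKO-106. Normalised expression was 9.70 ± 0.523 CPM (counts scaled to library size) in WT and 5.52 ± 1.28 CPM in IRF8-cKO (mean ± SD, n = 3 each). The log2 fold change was -0.81 (SE 0.33), which did not pass in the genome-wide edgeR test (adjusted p = 0.174). An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow. Liver tissue also holds Irf8 transcripts of immune cells, and a gene-level count does not show whether an exon was deleted.

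Lists of immediate-early genes, of inflammatory genes with neutrophil-attracting chemokines among them, and of neutrophil markers were lower in IRF8-cKO than in WT livers, with medians from -1.85 to -2.23 on the log2 scale. These list calls were made with a preset correlation between genes and did not hold with an estimated one (adjusted p 0.388 to 0.469), and 6 of 31, 7 of 31 and 6 of 21 members passed singly. Several interferon-stimulated genes, 5 of 20 clock genes, Fabp1 and Angptl4 were lower as well. Genes that rose included Paqr9, Inhbe, Dtx3l and the peroxisomal enzyme gene Ehhadh. Kupffer cell markers, from the resident macrophages of the liver, had a median of 0.84, but 0 of 12 members passed, the list means of the groups overlapped, and the list call did not hold with an estimated correlation (adjusted p = 0.682). Of 13134 genes tested, 182 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 59 higher and 123 lower in IRF8-cKO, all 182 by more than 2-fold.

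Among the genes that rose, Cxcl13, a chemokine that attracts B cells, had the largest log2 fold change taken under the naming rule, 5.33 (SE 1.05, adjusted p = 0.0495). It stood at 0.245, 0.259 and 0.133 CPM in WT-14, WT-44 and WT-77, a few reads each, and at 21.3, 2.10 and 2.97 CPM in IRF8-cKO-71, IRF8-cKO-88 and IRF8-cKO-106. Paqr9 (ENSMUSG00000064225, chromosome 9, 95559657 to 95568023) rose 8.34-fold, from 51.7 ± 10.9 to 431 ± 223 CPM (SD, n = 3; log2 fold change 3.06, SE 0.41, adjusted p = 0.0243). Inhbe, which encodes an inhibin subunit secreted by hepatocytes, rose 9.85-fold from 11.5 ± 3.23 to 114 ± 80.8 CPM (adjusted p = 0.0408). Dtx3l, encoding a ubiquitin ligase partner of PARP9, rose 6.34-fold (adjusted p = 0.0243). Other genes taken by rank were Zfp750, Anks4b, Zfp324, Invs, Hykk, Zbtb40 and Ap5b1, with log2 fold changes from 4.10 for Zfp750 to 2.38 for Ap5b1. With 1 library left out, some folds of rising genes moved by more than 1.5 times. Log2 fold changes were 3.55 for Cxcl13, 3.14 for Anks4b (3.75 on all 6 libraries) and 2.24 for Hykk (2.90) without IRF8-cKO-71, 2.63 for Inhbe (3.30) without IRF8-cKO-88, and 5.03 for Zfp750 and 3.78 for Zfp324 (3.16) without WT-14.

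Among the genes that fell, Csf3, encoding granulocyte colony-stimulating factor, had the largest change, with a log2 fold change of -6.77 (SE 0.92, adjusted p = 0.0243). It stood at 3.06, 10.5 and 19.3 CPM in WT-14, WT-44 and WT-77 and at 0, 0.185 and 0.093 CPM in IRF8-cKO-71, IRF8-cKO-88 and IRF8-cKO-106. Gadd45a, a stress gene induced by p53, fell 54.4-fold from 156 ± 94.2 to 2.84 ± 2.30 CPM (adjusted p = 0.0446). Ch25h, encoding cholesterol 25-hydroxylase, fell 24.0-fold, and Rnd1, a small GTPase gene, fell 21.0-fold. The other genes taken by rank, mt-Atp8, Fosb, Dppa3, Cxcl2, Tmem252, Ngp, Tnfrsf9 and Cxcl3, had log2 fold changes between -5.06 and -4.27. mt-Atp8 overlaps mt-Atp6 on the mitochondrial genome, so reads may be shared and its count is uncertain. With 1 library left out, folds of falling genes also moved by more than 1.5 times. Without IRF8-cKO-88 the log2 fold change was -7.52 for Csf3, -5.94 for Ch25h (-4.59 on all 6 libraries), -5.85 for Cxcl2 (-4.50), -5.95 for Tmem252 (-4.44), -6.05 for Ngp (-4.41) and -5.43 for Tnfrsf9 (-4.35). It was -6.16 for Fosb (-4.92) and -7.84 for Dppa3 (-4.92) without IRF8-cKO-106, -6.09 for Csf3, -3.58 for Rnd1 (-4.39) and -4.30 for mt-Atp8 (-5.06) without WT-77, and -3.71 for Tnfrsf9 without WT-14. Csf3, Dppa3, Ngp and Tnfrsf9 had no read in IRF8-cKO-71, so their fitted folds depend on the handling of zeros. Of the genes taken by the naming rule, 58 passed over all genes tested, and 0 of these 58 passed without WT-44 and 0 without WT-77.

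The count of changed genes rested on single libraries. Without WT-77, edgeR called 0 genes (smallest adjusted p 0.152, 1988 genes at an unadjusted p under 0.05, 451 called by DESeq2 and 0 by limma-voom), and without WT-44 it called 1. It called 20 without IRF8-cKO-106 and 1205 without IRF8-cKO-88, and the 59 higher calls became 32 without WT-14. Among genes taken by the naming rule that did not pass on all 6 libraries, 26 passed without IRF8-cKO-88, 3 without IRF8-cKO-71 and 2 without WT-14. On all 6 libraries DESeq2 called 1350 genes, including all 182, and limma-voom called 111. With library totals in place of composition factors, 82 genes were called, 39 higher and 43 lower, and the median log2 fold change of all genes moved from 0.03 to 0.25. The CPM of the groups did not overlap for 28.9% of tested genes, nor for any of the 182, where a call itself favours genes without overlap. By chance the share is 10% on average. Genes move together, so the share in a single division of the libraries can lie far from that average. It was not computed for other divisions. WT libraries correlated with each other at Pearson r 0.953 to 0.963 across genes, IRF8-cKO libraries at 0.905 to 0.944. WT-14 and IRF8-cKO-88 correlated at 0.945, above the 0.905 between IRF8-cKO-71 and IRF8-cKO-88.

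**Figure D1:**
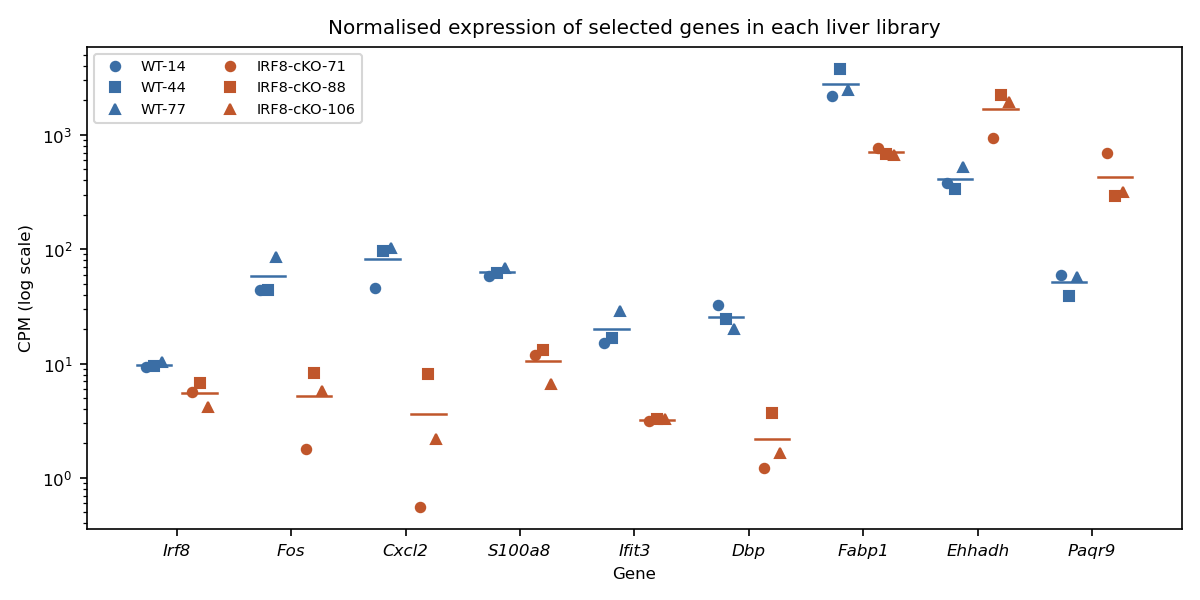
CPM on a log scale of 9 genes in each library, with WT in blue, IRF8-cKO in orange, 1 point per library and a horizontal line at the mean of each group. Irf8 lies between 9.32 and 10.3 CPM in WT and between 4.17 and 6.72 CPM in IRF8-cKO; Fos, Cxcl2, S100a8, Ifit3, Dbp and Fabp1 are lower and Ehhadh and Paqr9 higher in each IRF8-cKO library, and Csf3, with a library at 0, is not drawn.

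Of 41 gene lists drawn up before the data were examined, 39 had at least 5 tested members and were compared with all other genes by camera. With a preset correlation between genes, 18 lists changed, 16 lower and 2 higher. With an estimated correlation 0 of the 18 calls held (smallest adjusted p 0.388, 3 lists at an unadjusted p under 0.05), and fry, which asks whether the genes of a list move on balance one way, called 2. Every other division of the 6 libraries into 3 and 3 also gave called lists, from 9 to 19 against 18 in the real one. A list call with the preset correlation thus does not by itself tell the genotype groups from mixed groups. Below, a list said to fall has a negative median and such a call.

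Immediate-early and early growth genes, the fast transcriptional response to stress and growth signals, fell in IRF8-cKO. Over all genes tested 6 of 31 measured members fell, 0 rose and 25 did not pass, while 26 fell adjusted over the list alone. The median log2 fold change was -2.23 (camera adjusted p = 1.37e-15; adjusted p = 0.469 with an estimated correlation). Fos fell from 57.9 ± 24.2 to 5.25 ± 3.24 CPM (log2 fold change -3.46, SE 0.54, adjusted p = 0.0339), Fosb fell 30.4-fold (log2 fold change -4.92; -6.16 without IRF8-cKO-106), Gadd45b 8.88-fold and Ier5 3.46-fold. IRF8-cKO-71 stood apart in this list, with a mean log2 CPM of -2.60 relative to the mean of the 6 libraries, against -0.40 and -0.85 in IRF8-cKO-88 and IRF8-cKO-106.

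Inflammatory cytokines, chemokines and NF-kB targets fell as a group, with 7 of 31 members lower, 0 higher and 24 not passing, and 22 lower adjusted over the list alone. The median was -2.03 (camera adjusted p = 6.15e-14; adjusted p = 0.388 with an estimated correlation; fry adjusted p = 0.0327). The neutrophil chemoattractant genes Cxcl2 and Cxcl3 fell 22.7-fold and 19.3-fold (Cxcl2 57.7-fold without IRF8-cKO-88), and Ccl7, a monocyte chemoattractant, fell 5.39-fold (adjusted p = 0.0311). Lif fell 14.1-fold, and Il1b, encoding interleukin-1 beta, fell 3.33-fold from 14.5 ± 4.45 to 4.37 ± 0.403 CPM (adjusted p = 0.0472). Cxcl1 (-2.66, SE 0.69, adjusted p = 0.0839), Ccl2 (-2.03, SE 0.53, adjusted p = 0.0762) and Il6 (-3.45, SE 1.27, adjusted p = 0.153) had negative log2 fold changes that did not pass. Without IRF8-cKO-88 Cxcl1 stood at -3.58 (adjusted p = 0.0112) and Il6 at -6.28 (adjusted p = 0.0367), without WT-14 Il6 stood at -2.86, and without IRF8-cKO-106 Ccl2 stood at -2.80. Il6 overlapped between the groups, at 0.173 CPM in WT-44 and 0.679 CPM in IRF8-cKO-88. Tnf was below the expression filter, with 4 to 13 reads per library.

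Neutrophil markers fell, with 6 of 21 members lower, 0 higher and 15 not passing, and 19 lower adjusted over the list alone. The median was -1.85 (camera adjusted p = 1.16e-12; adjusted p = 0.469 with an estimated correlation). Relative to the mean of the 6 libraries, IRF8-cKO-88 stood apart from the other IRF8-cKO libraries, with a list mean of -0.26 against -1.33 and -1.59, and WT libraries ranged from 0.65 in WT-14 to 1.33 in WT-77. S100a8 (ENSMUSG00000056054), an abundant neutrophil calcium-binding protein gene, fell 5.96-fold from 63.1 ± 5.05 to 10.6 ± 3.48 CPM (log2 fold change -2.57, SE 0.32, adjusted p = 0.0243), and its partner S100a9 fell 5.17-fold. Retnlg fell 8.30-fold (14.4-fold without IRF8-cKO-88), and the granule protein genes Ltf and Ngp fell 19.2-fold and 21.2-fold (Ngp 66.1-fold without IRF8-cKO-88). Erythroid and platelet markers fell along with them: 1 of 10 members was lower, 0 higher and 9 not passing, and 7 were lower adjusted over the list alone. Their median was -1.39 (camera adjusted p = 5.32e-04; adjusted p = 0.388 with an estimated correlation; fry adjusted p = 0.0327). The haemoglobin gene Hba-a2 fell 3.35-fold (adjusted p = 0.0495), while Hba-a1 (-1.54, adjusted p = 0.0583), Ppbp (-2.60, adjusted p = 0.0627; -1.91 without WT-77) and Itga2b (-1.83, adjusted p = 0.0665) did not pass.

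Type I interferon-stimulated genes fell, with 3 of 38 members lower, 0 higher and 35 not passing. Adjusted over the list alone, 12 were lower and 2 higher. The median was -0.68 (camera adjusted p = 2.08e-04; adjusted p = 0.487 with an estimated correlation). Ifit3 fell 6.23-fold from 20.2 ± 7.53 to 3.23 ± 0.0783 CPM (adjusted p = 0.0243), Mx2 4.08-fold and Irf7, the interferon-amplifying IRF, 2.46-fold (adjusted p = 0.0446). Ifit1 did not pass (-1.84, adjusted p = 0.0531). The list of interferon-gamma-induced GTPases and chemokines fell with a median of -1.03 (camera adjusted p = 0.00271; adjusted p = 0.487 with an estimated correlation). Its 22 members gave 0 calls over all genes tested and 6 lower adjusted over the list alone, with Gbp3 at -1.67 (adjusted p = 0.0539), Cd274 at -2.24 (adjusted p = 0.0554; -2.97 without IRF8-cKO-88) and Cxcl10 at -2.88 (adjusted p = 0.0948). In this list the mean of WT-77 was 0.83 relative to the mean of the 6 libraries, against 0.13 and 0.19 in WT-14 and WT-44. Cxcl10 rested on WT-77, at 41.7 CPM against 7.23 and 4.14 CPM in WT-14 and WT-44, and stood at -1.25 without it. MHC class I antigen presentation fell by a median of -0.47 with 0 of 20 members passing and 2 lower adjusted over the list alone (camera adjusted p = 0.00576; adjusted p = 0.497 with an estimated correlation). The immunoproteasome gene Psmb10 stood at -1.33 (adjusted p = 0.0531). Neither MHC class II genes (9 members, 0 passing over all genes and 0 adjusted over the list alone, median -0.21, camera adjusted p = 0.400, H2-Eb1 -0.58) nor the IRF family passed. Of 8 IRF genes, 4 had negative log2 fold changes and Irf7 alone passed, also when adjusted over the list alone (median 0.03, mean -0.07 and test on the lower side, camera adjusted p = 0.520).

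The Kupffer cell list was called higher with the preset correlation, with all 12 members at positive log2 fold changes and a median of 0.84 (camera adjusted p = 0.00457; adjusted p = 0.682 with an estimated correlation; fry adjusted p = 0.299). Over all genes tested 0 of 12 passed, and 2 were higher adjusted over the list alone. Cd5l was 17.4 ± 3.78 CPM in WT and 45.0 ± 20.6 CPM in IRF8-cKO (log2 fold change 1.37, SE 0.36, adjusted p = 0.0784), Vsig4 stood at 1.70 (adjusted p = 0.0888; 1.08 without IRF8-cKO-71), Marco at 1.42 (0.76 without IRF8-cKO-71) and Clec4f at 0.96. Relative to the mean of the 6 libraries, the list mean was 0.90 and 0.65 in IRF8-cKO-71 and IRF8-cKO-88 but -0.39 in IRF8-cKO-106, below WT-14 (-0.15) and WT-44 (-0.34), and the call was lost without IRF8-cKO-88 (adjusted p = 0.0567). Cholangiocyte markers, from the bile duct epithelium, fell with a median of -1.56 (camera adjusted p = 2.19e-05; adjusted p = 0.469 with an estimated correlation). WT-77 stood apart in this list, with a mean of 1.35 on the same scale against 0.67 and 0.15 in WT-14 and WT-44. Of 13 cholangiocyte genes 0 passed over all genes and 9 were lower adjusted over the list alone, with Krt19 at -3.47 (adjusted p = 0.0551; -2.21 without WT-77), Epcam at -2.48 (adjusted p = 0.0602), Cldn7 at -2.47 (adjusted p = 0.0646; -1.84 without WT-77) and Spp1, also expressed by macrophages, at -1.70 (adjusted p = 0.0606).

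The remaining cell type lists did not pass. Monocyte and macrophage markers had a median of -0.69 (19 members, 0 passing over all genes and 0 adjusted over the list alone, camera adjusted p = 0.0973), with Adgre1 at 1.76 (adjusted p = 0.0796), and the list passed as lower without WT-44 (adjusted p = 0.0284) and without IRF8-cKO-88 (adjusted p = 0.0117), and with the 1 CPM filter (adjusted p = 0.0486). Dendritic cell markers had a median of -0.15 (12 members, 0 passing, 1 lower adjusted over the list alone, camera adjusted p = 0.489), with Bst2 at -1.16. T and NK cell markers had a median of -0.01 and a mean of 0.15 (10 members, 0 passing either way, camera adjusted p = 0.637), with Cd8a at 1.43 (0.80 without WT-14 and 2.38 without WT-44). Both medians were above 0 with library totals only, as was that of the 4 B cell markers, too few for a test, at -0.23 with Ighm at -1.40. Sinusoidal endothelial markers had a median of 0.14 (23 members, 0 passing, 2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.301), with Wnt2 at 2.18 (adjusted p = 0.0557), and passed as a list without WT-77 (adjusted p = 0.0253). Among 21 stellate cell and fibroblast markers Timp1, the tissue inhibitor of metalloproteinases, fell 4.81-fold (adjusted p = 0.0339), and adjusted over the list alone it was again 1 lower. That list had a median of -0.11, above 0 with library totals only (camera adjusted p = 0.504).

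**Figure D2:**
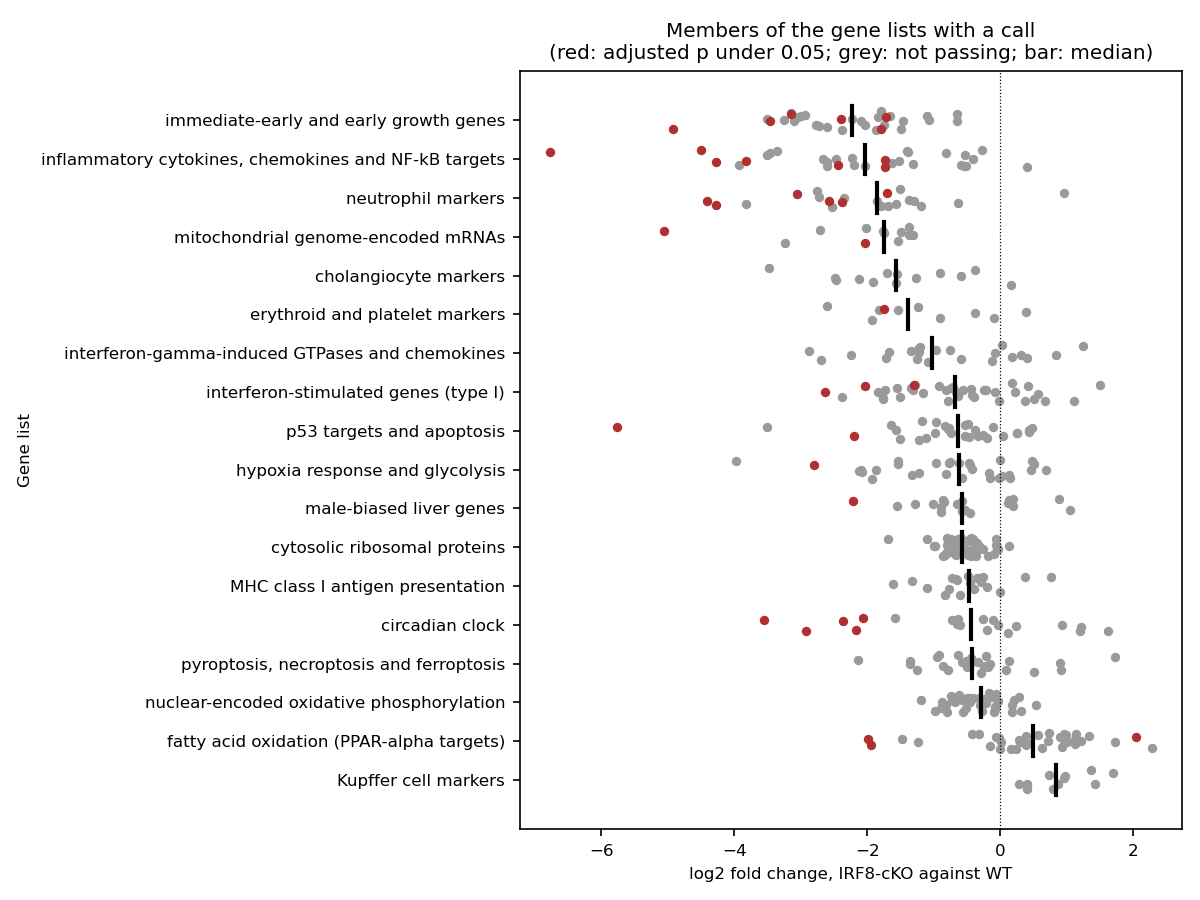
Log2 fold change of IRF8-cKO against WT for each tested member of the 18 lists with a call, 1 point per gene, red where the adjusted p over all genes was under 0.05 and grey otherwise, with a black bar at the list median; points are spread vertically for visibility. Medians run from -2.23 for immediate-early genes to 0.84 for Kupffer cell markers, and most members of each list are grey.

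The list of fatty acid oxidation genes driven by PPAR-alpha was called higher with the preset correlation (median 0.49, camera adjusted p = 0.0145; adjusted p = 0.487 with an estimated correlation; fry adjusted p = 0.237), while single members went both ways. The list means of the groups overlapped, with IRF8-cKO-71 (-0.17 relative to the mean of the 6 libraries) below WT-44 (-0.12) and WT-77 (0.08). Over all genes tested 1 of 36 rose, 2 fell and 33 did not pass, against 6 higher and 2 lower adjusted over the list alone. Ehhadh, encoding the peroxisomal bifunctional enzyme, rose 4.12-fold from 412 ± 95.8 to 1698 ± 671 CPM (adjusted p = 0.0446). The fatty acid binding protein gene Fabp1 fell 3.98-fold from 2801 ± 849 to 704 ± 49.8 CPM (adjusted p = 0.0408), and Angptl4, an inhibitor of lipoprotein lipase, fell 3.86-fold (adjusted p = 0.0446). Vnn1 stood at 1.22 (adjusted p = 0.0583). The list was not called without WT-14 (adjusted p = 0.102) or without IRF8-cKO-88 (adjusted p = 0.184).

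Other hepatocyte programmes did not pass as lists. Acacb, an acetyl-CoA carboxylase gene, rose 3.09-fold (adjusted p = 0.0495), 1 of 26 genes of fatty acid and triglyceride synthesis, with 4 higher and 2 lower adjusted over the list alone (median -0.08, above 0 with library totals only, camera adjusted p = 0.715). In the list of hepatocyte secreted and identity genes Serpina6, encoding corticosteroid-binding globulin, fell 4.89-fold. Of 33 members 1 was higher, 1 lower and 31 did not pass, 1 was higher and 2 lower adjusted over the list alone, and the median was -0.36 (camera adjusted p = 0.123; 0.0469 without WT-14). Alb was 73926 ± 13649 CPM in WT and 51987 ± 6184 CPM in IRF8-cKO (adjusted p = 0.412). Mbl2, encoding mannose-binding lectin, fell 3.00-fold (adjusted p = 0.0408), the only 1 of 33 complement and coagulation genes to pass both over all genes and adjusted over the list alone (median -0.26, camera adjusted p = 0.0620; 0.00125 without IRF8-cKO-71 and 0.0444 with the 1 CPM filter). Socs3, a feedback inhibitor of interleukin-6 signalling, fell 6.18-fold (adjusted p = 0.0381) in the list of 30 acute-phase proteins, where 2 were lower adjusted over the list alone and the median was 0.64 (camera adjusted p = 0.400; 8.43e-04 as higher without IRF8-cKO-106). Saa1 was 2384 ± 1083 CPM in WT and 4445 ± 5355 CPM in IRF8-cKO (log2 fold change 0.90, adjusted p = 0.552; -0.77 without IRF8-cKO-71).

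Cholesterol synthesis (24 members, median 0.09, camera adjusted p = 0.988, with the test on the lower side, Sqle 1.64, and 0.81 without IRF8-cKO-71) gave 0 calls over all genes and 0 adjusted over the list alone. Bile acid synthesis and transport (24 members, median 0.00 with a sign that turned with median-of-ratios scaling, test on the lower side, camera adjusted p = 0.520) gave 0 calls over all genes, and 2 higher and 4 lower adjusted over the list alone. Slc51b stood at -3.06 (adjusted p = 0.0513) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.66 (SE 0.92, adjusted p = 0.693; -1.59 without IRF8-cKO-71). Drug-metabolising cytochromes P450 gave 0 calls of 29 either way (median -0.35, camera adjusted p = 0.128, Cyp2c39 2.73, and 3.76 without WT-44). Gluconeogenesis and urea cycle genes gave 0 calls of 21 over all genes, and 1 higher and 4 lower adjusted over the list alone (median -0.17, above 0 with library totals only, camera adjusted p = 0.318), with Gpt2 at 1.34 (adjusted p = 0.0554).

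Autophagy and lysosome genes did not pass as a list or singly: 0 of 43 passed over all genes and 0 adjusted over the list alone (median 0.13, camera adjusted p = 0.172; fry adjusted p = 0.0557). The list means of the groups did not overlap, at 5.49 to 5.56 log2 CPM in WT and 5.67 to 5.71 in IRF8-cKO. Log2 fold changes were positive for 24 members and negative for 19. Becn1, a core initiator of autophagy, was 32.5 ± 0.438 CPM in WT and 30.0 ± 4.40 CPM in IRF8-cKO (log2 fold change -0.12, SE 0.24, adjusted p = 0.795), and its sign turned with library totals only. Map1lc3b stood at 0.09 (SE 0.29, adjusted p = 0.873), Sqstm1 at 0.36 (SE 0.39, adjusted p = 0.602) and Atg2b, the member with the lowest p, at 1.04 (SE 0.30, adjusted p = 0.0888).

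The list of hypoxia response and glycolysis genes fell (median -0.62, camera adjusted p = 2.08e-04; adjusted p = 0.437 with an estimated correlation), with 1 of 31 lower, 0 higher and 30 not passing, and 11 lower adjusted over the list alone. Log2 fold changes were negative for 24 members and positive for 7. Genes of glycolytic enzymes went both ways, with Pgam1 at 0.69, Tpi1 at 0.51 and Ldha at 0.47 but Pkm at -1.33 and Gapdh at -3.97, none passing. The lactate exporter gene Slc16a3 fell 6.93-fold (adjusted p = 0.0383), while Pfkfb3 (-1.54, adjusted p = 0.0554), Ndrg1 (-1.93, adjusted p = 0.0678; -2.61 without IRF8-cKO-88) and Slc2a1 (-2.09, adjusted p = 0.0719) did not pass. Targets of p53 and apoptosis genes fell (median -0.64, camera adjusted p = 5.24e-04; adjusted p = 0.469 with an estimated correlation), with 2 of 30 lower, 0 higher and 28 not passing, and 8 lower adjusted over the list alone. These 2 were Gadd45a and Trp53inp1, a p53-induced stress gene that fell 4.59-fold (adjusted p = 0.0495). The anti-apoptotic gene Bcl2l1 stood at -1.64 (adjusted p = 0.0855). The pyroptosis, necroptosis and ferroptosis list was called lower with the preset correlation, with a median of -0.42 (camera adjusted p = 0.0354; adjusted p = 0.487 with an estimated correlation), and 0 of its 27 members passed either over all genes or adjusted over the list alone. Relative to the mean of the 6 libraries, IRF8-cKO-88 (0.14) was level with WT-14 (0.15), against -0.55 and -0.30 in IRF8-cKO-71 and IRF8-cKO-106. Members with the lowest p went both ways, with Pycard at -2.14, Casp4 at -1.35, the iron exporter gene Slc40a1 at 1.72 and Tfrc at 0.91. This list was not called without WT-14 (adjusted p = 0.0605), WT-44 (0.0514), IRF8-cKO-71 (0.133) or IRF8-cKO-106 (0.0813), nor with the 1 CPM filter (0.0986) or, in settings chosen after the data were seen, a correction for gene length (0.0686) or for length and GC content (0.0560).

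Unfolded protein and integrated stress response genes had a median of 1.08 and did not pass as a list (camera adjusted p = 0.128), with 2 of 28 higher, 1 lower and 25 not passing, and 11 higher and 2 lower adjusted over the list alone. Sel1l, part of the machinery that degrades misfolded proteins of the endoplasmic reticulum, rose 4.83-fold (adjusted p = 0.0446) and Ppp1r15a, the stress-induced phosphatase subunit GADD34, fell 4.51-fold (adjusted p = 0.0408). Without IRF8-cKO-106 the list passed as higher (adjusted p = 5.95e-06). In the heat shock list Chordc1 rose 3.36-fold (adjusted p = 0.0446), 1 of 20 members over all genes and 1 adjusted over the list alone (median 0.42, camera adjusted p = 0.135; 0.0157 without IRF8-cKO-88). NRF2 targets gave 0 calls of 29 either way (median -0.10, above 0 with library totals only, camera adjusted p = 0.318; 0.00109 without IRF8-cKO-106), with Gsta3 at -1.22. Cell cycle and DNA replication genes gave 0 calls of 25 over all genes and 1 lower adjusted over the list alone (median -0.38, camera adjusted p = 0.0733; 0.0356 without WT-44, 0.00650 without IRF8-cKO-106 and 0.0417 with the length and GC correction), with Tk1 at -2.53 (adjusted p = 0.0591).

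The circadian clock list was called lower with the preset correlation (median -0.43, camera adjusted p = 0.0241; adjusted p = 0.487 with an estimated correlation), with 5 of 20 lower, 0 higher and 15 not passing, and 3 higher and 6 lower adjusted over the list alone. Members went both ways, with 14 negative and 6 positive log2 fold changes. Arntl, Clock, Npas2, Nfil3 and Cry1 had a median of 0.94, with 3 of 5 above 0. A group of 11 others, with Dbp, Nr1d1, Bhlhe41 and Ciart among them, had a median of -1.58, with 8 below 0. Dbp (ENSMUSG00000059824), a clock output transcription factor gene, fell 11.7-fold from 25.7 ± 6.44 to 2.20 ± 1.32 CPM (log2 fold change -3.55, SE 0.45, adjusted p = 0.0243). The clock repressor genes Nr1d1, Bhlhe41 and Ciart fell 5.12-fold, 7.53-fold and 4.51-fold. The list was not called without WT-77 (adjusted p = 0.0605) or IRF8-cKO-88 (adjusted p = 0.0758). Male-biased liver genes were called lower as a list with the preset correlation, with a median of -0.58 (camera adjusted p = 0.0358; adjusted p = 0.487 with an estimated correlation; fry adjusted p = 0.272). The list means of the groups overlapped, with WT-77 (-0.18 relative to the mean of the 6 libraries) below IRF8-cKO-88 (0.01). Hsd3b5, a male-specific steroid dehydrogenase gene, fell 4.63-fold (adjusted p = 0.0439), 1 of 19 with 0 higher and 18 not passing, and 5 were lower and 1 higher adjusted over the list alone. Mup20, encoding a major urinary protein, stood at -1.55 (adjusted p = 0.0678), Slco1a1 at -0.86 and Cyp4a12b at 1.05. This call was lost without WT-14 (adjusted p = 0.0600), WT-44 (0.114) or IRF8-cKO-106 (0.193), and with the correction for gene length (0.160) or for length and GC content (0.119). Female-biased liver genes gave 0 calls of 9 either way (median -0.15, above 0 with library totals only, camera adjusted p = 0.397, Nipal1 -1.67, and -2.47 without IRF8-cKO-106). All 6 libraries held male RNA, with 0 to 2 Xist reads and 888 to 1995 Ddx3y reads each. The 4 sex chromosome genes with enough reads gave 0 calls either way and had a median of 0.37, with Uty at 0.69 (adjusted p = 0.201) and Ddx3y at 0.06 (adjusted p = 0.921).

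Genes encoding cytosolic ribosomal proteins were called lower as a list with the preset correlation, with 53 of 54 at negative log2 fold changes, a median of -0.58 and 0 members passing over all genes or adjusted over the list alone (camera adjusted p = 8.62e-07; adjusted p = 0.710 with an estimated correlation). Relative to the mean of the 6 libraries, the list mean was nearly equal in WT-14 (0.04) and IRF8-cKO-71 (-0.01), while WT-44 (0.51) and IRF8-cKO-106 (-0.59) stood at the ends. The same libraries were at the ends for the shortest of 10 length classes of genes (median log2 CPM of the class on that scale 0.45 and -0.38). Rpl38 was 162 ± 59.6 CPM in WT and 81.2 ± 22.2 CPM in IRF8-cKO, and Rps23 stood at -0.99, Rps19 at -0.83 and Rpl22 at -0.75. mRNAs encoded by the mitochondrial genome fell with a median of -1.75 (camera adjusted p = 6.67e-06; adjusted p = 0.487 with an estimated correlation), with 2 of 13 lower, 0 higher and 11 not passing, and 13 lower adjusted over the list alone. mt-Nd3, a complex I subunit gene, fell 4.10-fold (adjusted p = 0.0482), and mt-Co2 (-2.01, adjusted p = 0.0719) and mt-Atp6 (-3.23, adjusted p = 0.0768) did not pass. Both passed without WT-14 (adjusted p = 0.0378 and 0.0327). Mean CPM in WT was 9.44 for mt-Atp8, 59.9 for mt-Nd3, 553 for mt-Co2 and 1117 for mt-Atp6, against 58801 for mt-Co1 and 31430 for mt-Cytb. Whether multiply mapped reads of the low genes were lost is unknown, so their folds are uncertain. The abundant mt-Co1 (-1.30, adjusted p = 0.145) and mt-Cytb (-1.36, adjusted p = 0.141) did not pass. mt-Atp6 stood at 2199 CPM in WT-44 and 156 CPM in WT-14, and at -2.29 without WT-44. Mitochondrial genes took 7.19%, 20.2% and 14.5% of reads in WT-14, WT-44 and WT-77 and 5.99%, 7.14% and 6.01% in IRF8-cKO-71, IRF8-cKO-88 and IRF8-cKO-106. Nuclear-encoded oxidative phosphorylation genes were called lower as a list with the preset correlation, with a median of -0.29 and 0 of 42 members passing either way (camera adjusted p = 0.0145; adjusted p = 0.761 with an estimated correlation; fry adjusted p = 0.427), with Ndufa1 at -1.19, Ndufa2 at -0.98, Cox6c at -0.88 and Cox8a at -0.80. The list means of the groups overlapped, with IRF8-cKO-71 (0.16 relative to the mean of the 6 libraries) above WT-14 (0.12) and WT-77 (-0.11). That call was lost without WT-44 (adjusted p = 0.199), IRF8-cKO-88 (0.0758) or IRF8-cKO-106 (0.265). Log2 fold changes rose with gene length across genes (Spearman 0.196), and in a fit with a gene length correction, chosen after the data were seen, the medians of the ribosomal, mitochondrial and nuclear oxidative phosphorylation lists were -0.38, -1.18 and -0.15, the last no longer called (adjusted p = 0.217).

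**Figure D3:**
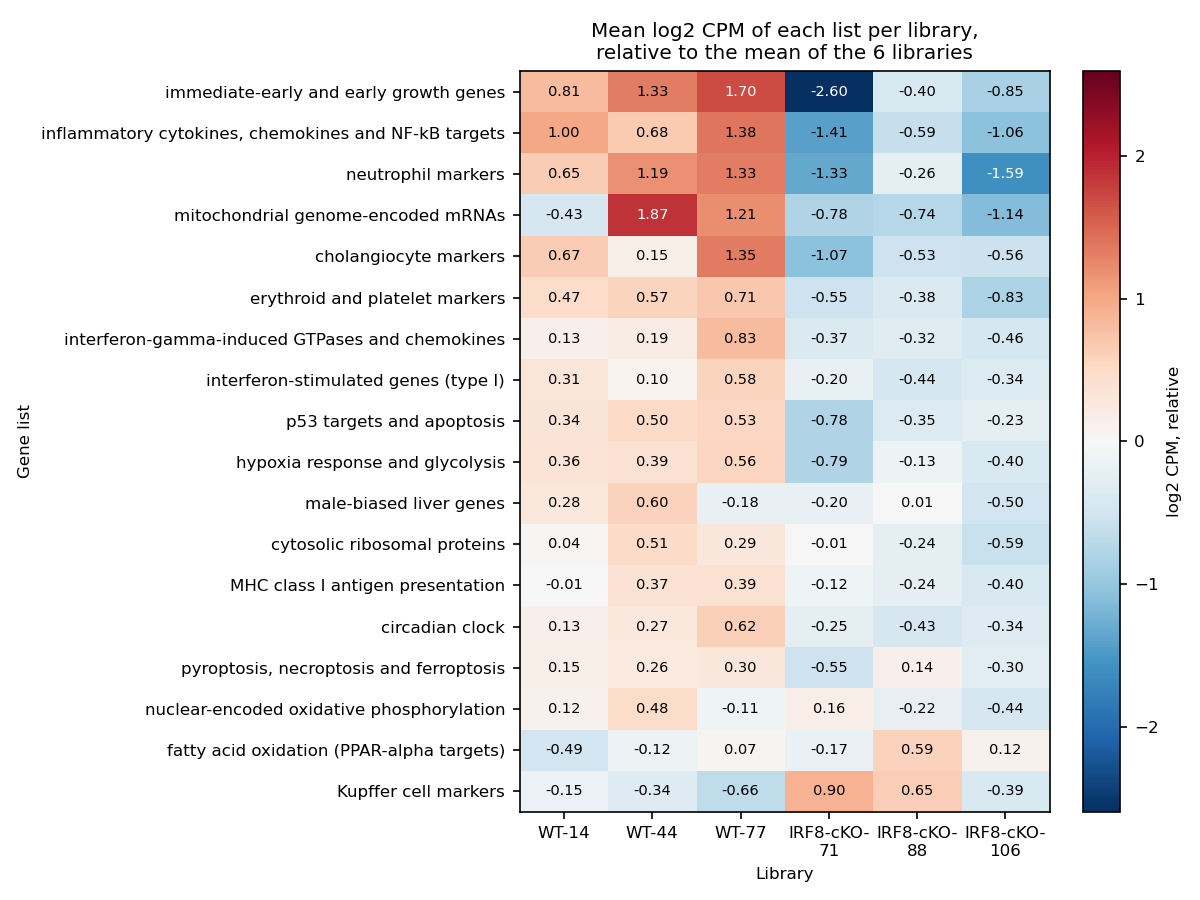
Mean log2 CPM of the tested members of each list with a call (rows) in each library (columns), relative to the mean of the 6 libraries, with red above and blue below that mean. Immediate-early genes range from 1.70 in WT-77 to -2.60 in IRF8-cKO-71, and mitochondrial mRNAs are at -0.43 in WT-14 but 1.87 and 1.21 in WT-44 and 77.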

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

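The gene length, length with GC content and mitochondrial gene settings were chosen after the data were seen. The count of 182 changed genes (59 higher, 123 lower, 182 more than 2-fold) was within 1.5 times under median-of-ratios or upper-quartile scaling, the 1 CPM filter, no robust shrinkage, and removal of the 10 genes with most reads or of mitochondrial genes. It was 82 with library totals only (39 higher, 43 lower, 82 more than 2-fold), 1723 without a low-count filter (817, 906 and 1654), 1350 with DESeq2 (583, 767 and 1299), 111 with limma-voom (23 higher, 111 more than 2-fold) and 665 with library weights (276, 389 and 658). It was 77 with the length correction (21, 56 and 77) and 73 with length and GC (20, 53 and 73). The cause was not tested in any of these. With 1 library left out, which also lowers the number of samples, changed genes ranged from 0 to 1205, higher from 0 to 575, lower from 0 to 630 and those over 2-fold from 0 to 1205. The ends are WT-77 and IRF8-cKO-88. The 18 called lists became 0 with an estimated correlation and 2 with fry. With 1 library left out 16 to 19 lists were called, of which 14 to 17 were among the 18, with 14 without IRF8-cKO-88 and 15 without WT-14, WT-44 or IRF8-cKO-106. The length correction gave 15 lists and length with GC 16, each with 15 of the 18. Among the 58 called genes taken by the naming rule, the fold of 17 moved by more than 1.5 times with 1 library left out, most often IRF8-cKO-88 (8 genes). Of the 58 called genes taken by the naming rule, 34 remained called with library totals only, 38 with limma-voom, 23 with length and GC, 58 with DESeq2, 30 without WT-14, 0 without WT-44 or WT-77, 41 without IRF8-cKO-71, 57 without IRF8-cKO-88 and 5 without IRF8-cKO-106. None of the 182 called genes and none of the 18 called lists changed sign in the settings run in which they had a value. For the genes this was to be foreseen and adds little. All 182 had CPM that did not overlap between the groups and absolute log2 fold changes of at least 1.26. Among uncalled named genes 14 of 1169 values changed sign. Irf8, whose CPM did not overlap between the groups either, kept its negative log2 fold change in each setting run, from -0.98 to -0.63 with 1 library left out. No paired analysis was possible because the groups share no replicate numbers. Depth limits genes with few reads, such as Tnf at 4 to 13 reads per library.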

Other observations

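The IRF8-cKO libraries differed among themselves in programmes that did not separate the groups. Relative to the mean of the 6 libraries, the mean log2 CPM of acute-phase genes was 0.86 in IRF8-cKO-71, 0.19 in IRF8-cKO-88 and -0.84 in IRF8-cKO-106. Saa1, a major acute-phase gene, stood at 10561, 2177 and 598 CPM in these libraries and at 3591, 1497 and 2063 CPM in WT-14, WT-44 and 77. Cholesterol synthesis genes were at 0.81 in IRF8-cKO-71, with Sqle at 108 CPM against 15.1 to 35.7 CPM elsewhere, and at -0.54 and -0.16 in IRF8-cKO-88 and IRF8-cKO-106. Unfolded protein and integrated stress response genes were at 1.07 in IRF8-cKO-88 and -0.78 in IRF8-cKO-106. NRF2 targets, an antioxidant programme, were at -0.84 in IRF8-cKO-71 and 0.81 in IRF8-cKO-106. Cyp7a1 was at 25.9 CPM in IRF8-cKO-71 and 1.30 to 7.31 CPM in the others. These are values of single libraries without a test.

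Tests of gene length, blood genes, Kupffer cell markers and clock arms below were chosen only after the result was seen; the tests that regroup the libraries were planned. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 182 changed genes and the highest other 0, and 182 against 0 for genes over 2-fold. For lists the real split gave 18 and the others from 9 to 19. As many genes came from 1 split (the real one) and as many lists from 2 splits, and 10 splits are too few for a share under 0.05.

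The joint fall of immediate-early, inflammatory and neutrophil genes was set against a gene length and GC content trend. The fall of the neutrophil list alone was also set against less blood in the sampled lobe and fewer leukocytes of every kind. Each test compared the groups in a mean log2 CPM per library, with a Welch 95% interval over libraries. After correction for length and GC the difference for the 83 members was -2.17 (-3.75 to -0.58), against -2.26 (-3.72 to -0.79) before. Their median log2 fold change moved from -2.08 to -1.98. As far as the correction models the trend, it took away a small part of the fall, which argues against that trend as the whole cause. The intervals measure the spread between libraries and not the share of the trend. The 3 lists were picked for their fall in this same comparison, so an interval below 0 was likely from the start. The next tests took the mean of the neutrophil list minus that of another set. Against the Kupffer cell list the difference was -2.88 (-4.37 to -1.40, and -3.20 to -2.49 with 1 library left out). That list was picked after all 12 members were seen at positive log2 fold changes, so a large difference was to be foreseen. The values show only that the neutrophil and Kupffer cell lists did not fall alike. Kupffer cells do not stand for every leukocyte kind. The monocyte and macrophage, dendritic cell, and T and NK cell lists (medians -0.69, -0.15 and -0.01) were not set against the neutrophil list. A smaller loss shared by all kinds stays open, since the Kupffer cell list itself did not separate the groups (0.76, interval -0.72 to 2.25) and was low in IRF8-cKO-106. Against 4 globin and 3 platelet genes the difference was -0.50 (-1.16 to 0.15), so less blood in the lobe stays open as an explanation of the neutrophil fall. The 7 genes leave out Alas2 (-0.09), Bpgm (0.39) and Ube2l6 (-0.38), members of the erythroid and platelet list that did not fall as the others did. Against the full list of 10 the difference was -0.95 (-2.02 to 0.12), with no overlap of the groups. The blood genes did not agree: against the 4 globin genes alone the difference was -0.76 (-1.37 to -0.15), against the 3 platelet genes -0.16 (-1.22 to 0.90). The genotype, different sampling or handling of the mice and chance remain open, and neither genotype nor handling was tested apart from the group.

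The clock genes invite the hypothesis that the groups were collected at different clock phases. The opposite arm holds the 5 called clock genes that prompted the hypothesis, so it was tested without them. The Arntl arm (Arntl, Clock, Npas2, Nfil3 and Cry1) had a median of 0.94 and the other 6 genes of the opposite arm (Nr1d2, Per1, Per2, Per3, Tef and Hlf) a median of -0.04, a difference of 0.97 (exact two-sided permutation of genes, p = 0.184; genes are not independent replicates). The expected sign held for 3 of 5 and 3 of 6 genes. With the 5 called genes put back, the opposite arm had a median of -1.58, with 8 of 11 genes below 0, and the difference was 2.51. That difference rests in part on the genes that prompted the hypothesis. Leaving them out takes only fallen genes from the opposite arm, which works against a difference. Neither version decides, and a phase difference stays open. After length and GC correction the mean log2 CPM of the 5 called clock genes differed by -2.47 (Welch interval over libraries -3.13 to -1.82), against -2.52 before. These 5 were picked as called in this same comparison, so an interval below 0 was likely from the start and decides nothing. The correction itself moved their difference little. Collection times are not given in the sources used here, and an effect of the genotype on clock genes remains open and untested.

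Lower ribosomal protein mRNAs, which are short, were set against the length and GC trend. The correction moved the group difference in the mean log2 CPM of the 54 members from -0.56 (Welch interval over libraries -1.17 to 0.06) to -0.40 (-0.83 to 0.04). The interval included 0 already before the correction, so it does not decide. The correction brought the median of the shortest class from -0.43 to -0.003 and left the list median at -0.37, still called with the preset correlation (camera adjusted p = 1.02e-04), which goes against the trend as the whole of the fall only as far as that preset holds. The trend stays open as a cause of a part of it. Median log2 fold changes ran from -0.43 in the shortest of 10 length classes to 0.20 in the longest. In median log2 CPM of the shortest class relative to the mean of the 6 libraries, WT-44 (0.45) and IRF8-cKO-106 (-0.38) stood at the ends, as they did for the ribosomal list (0.51 and -0.59), while WT-14 and IRF8-cKO-71 were nearly equal in that list (0.04 and -0.01). RNA quality and library preparation may add to this and were not tested.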
